A study of Mus musculus with 8 samples.

How the data were processed

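Gene expression was measured in liver tissue of 4 male C57BL/6J mice, named M24, M48, M50 and M60 in the labels. Per the labels' protocols, the mice had received an adeno-associated virus (AAV) vector at 2 to 3 months of age and were necropsied 18 months later. A tumor described as hepatocellular carcinoma and adjacent normal liver were taken from each mouse, which gave 4 tumor and 4 adjacent samples. The pieces were snap frozen, RNA was extracted with an RNeasy kit, and 0.2 ug of total RNA per sample was amplified and labelled with biotin. Each sample was hybridised to 1 Affymetrix mouse gene array, so the number of arrays limits the precision.

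The authors deposited 1 table of log2 expression values with 28874 probes, 8 sample columns and 0 missing values. The log base was taken from the range of the deposited values, whose lowest was 1.918 and highest 14.49. The 8 columns had nearly the same quantiles, with medians from 4.888 to 5.006, so the values were taken as already normalized between arrays. The submitters' processing notes name MAS5, with no version or role. The background correction, summarization and normalization steps are not given in the sources used here, nor are detection calls or scan dates, so neither detection per probe nor hybridisation batch was tested. No further scaling was applied in the main comparison.

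Gene names came from the annotation table of the array's probes. It listed 23410 probes, of which 21789 had 1 gene symbol and 1621 had several, and 5464 probes had no entry and were left unnamed. Of the single-symbol probes, 21698 were found by gene identifier in a reference table of assembly GRCm38.p6, and 0 symbols had to be changed. That table was used only for names, chromosome membership and gene order. Each of 19938 genes was represented by its single-symbol probe with the highest mean over the 8 arrays, which mattered for 999 genes with several probes. The 40% of genes with the lowest mean, which lay below a log2 value of 4.597, were left out, and 11963 genes were tested.

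Tumor and adjacent samples were compared with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3. The mouse entered as a block, because the design text says that both tissues were dissected from each of the same mice. Differences are tumor minus adjacent on the log2 scale over n = 4 pairs, with the standard error (SE) of that fit, 3 residual degrees of freedom and 3.643 prior degrees of freedom. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. As a check of the pairing, deviations from the group means were correlated across genes between the tissues of a mouse. The values were 0.313 in M24, 0.421 in M48, 0.0986 in M50 and 0.111 in M60, against -0.378 to 0.189 between different mice. Each group mean includes the sample itself, so positive values within mice push those between mice down.

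The 48 gene lists covered pathways, liver functions and markers of other cell types. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 48 lists. Camera was repeated with an estimated correlation, and fry was run as a self-contained test. For each list, members past the threshold over all genes were counted, together with the members that passed when p-values were adjusted over the list alone. With an estimated correlation, 0 of the 48 lists passed the threshold, and 6 had an unadjusted p under 0.05. That version rests on the 3 residual degrees of freedom and has little power over 48 lists. Its lowest unadjusted p was 0.0117, for the tumor and fetal liver markers. A list that fails there is therefore not shown to be unchanged. Fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, called 16 lists higher and 13 lower.

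The groups, the block, the lists, the threshold and the rule for naming genes were fixed before the data were examined. The rule took the 15 largest rises and 15 largest falls among genes past the threshold with the same sign in all 4 mice. It added up to 4 members with the smallest p of each list, the members of the imprinted Dlk1-Dio3 locus, and Xist and Y-linked genes as a check of sex. Genes named outside this rule were chosen after their values were seen. They are the other list members in the text, the low male-biased and high stress genes of M48 and the Klrb1 family.

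The fit was tested on simulated data built on the same 11963 genes, with 200 changed genes in each of 20 simulations. It recovered 41.4% of genes changed 1.5-fold, 77.9% of those changed 2-fold and 95.6% of those changed 4-fold, and 4.6% of the calls were false. A far larger share of genes, 31.9%, was called in the data, so these rates need not hold for the real fit. The list test called the changed list of 20 genes in 10 of 10 simulations. Among 47 unchanged lists in each of those simulations it made 2 false calls in all. The simulated noise was independent between genes and the lists were random, so this rate does not cover lists of genes regulated together.

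Alternatives were quantile normalization, median centring, no filter on low genes, a 60% filter, the mean of a gene's probes, every probe by itself and no block. Others were the mouse as a random block, eBayes without a trend or with robust variances, array weights, and leaving out each mouse. A looser threshold, a minimum fold of 2 and rank correlations were also tried. Figures were drawn with matplotlib.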

Results

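The data were 8 expression profiles of mouse liver, 4 from hepatocellular carcinomas and 4 from the adjacent liver of the same mice (M24, M48, M50 and M60), taken 18 months after injection of an AAV vector. The comparison asked how expression in the tumors differed from that of the adjacent tissue. All differences are tumor minus adjacent in log2 units over n = 4 pairs, and adjusted p-values are those of limma unless camera is named. A gene is said to have risen or fallen where its adjusted p was under 0.05.

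The tumors differed from the adjacent liver by very large changes in a small set of genes and by moderate changes in many. The largest rise was that of Akr1c18, a steroid dehydrogenase, at 8.51 (SE 0.144, adjusted p = 2.22e-06), from a mean level of 3.15 ± 0.134 (SD) in adjacent tissue to 11.65 ± 0.349 in tumors. That adjacent level lay below the filter value of 4.597 and the mean of the left-out genes, 3.527. It cannot be told from background, so the exact size of the rise is uncertain. The tetraspanin Tspan8 rose by 6.98 (SE 0.216), the surface protein Ly6d by 6.03 (SE 0.107) and carboxypeptidase E, a prohormone-processing enzyme (Cpe), by 6.01 (SE 0.137). Klrb1b, which encodes a lectin-like receptor of natural killer cells, rose by 5.82 (SE 0.36). The trefoil factor Tff3 rose by 5.28, the cystine transporter Slc7a11 by 4.95, the fatty acid desaturase Scd2 by 4.83 and E-cadherin (Cdh1) by 4.06. The other genes among the 15 largest rises were Tmem54, Gldn, D17H6S56E-5, Sprr1a, Cdh17 and Elapor1, with differences from 4.12 for Elapor1 to 5.15 for Tmem54. Adjacent means also lay below the filter value for Slc7a11 (3.38), Cdh17 (3.59), Gldn (3.76), Tmem54 (3.85), Cpe (4.17), Klrb1b (4.23) and Sprr1a (4.44). The exact sizes of these rises, and their order, are therefore uncertain too. The same holds for the sizes of rises given further below that start from such levels, among them Krt23 (3.98), Mki67 (4.13), Tnfrsf10b (4.22) and Afp (4.32).

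Cytochrome P450 genes were among the largest falls. The fatty acid hydroxylase Cyp4a14 fell by 5.46 (SE 0.747, adjusted p = 0.00294). Cyp2c37 fell by 5.26, Cyp2c54 and Cyp2c38 by 4.89 each, Cyp2c50 by 4.74 and Cyp2c29 by 3.67. The Cyp2c genes, like Cyp4a12a (-3.67) and Cyp4a12b (-3.66), are close copies of each other whose probes can share signal, so the value of each member is uncertain. The oxysterol hydroxylase Cyp7b1 fell by 4.12, the glutamate transporter Slc1a2 by 4.06 and Etnppl, an enzyme of phosphoethanolamine breakdown, by 4.04. Serpina4-ps1 (-4.35), the sulfotransferase Sult2a8 (-3.89) and Gm21286 (-3.76) also fell. The tumor means of Serpina4-ps1 (4.01) and Cyp2c38 (4.37) lay below the filter value, so the sizes of these 2 falls are uncertain. The fatty acid elongase Elovl3 fell by 4.03 (SE 1.05, adjusted p = 0.0276), but its difference was only -0.59 in M48, and its call was lost without M24 (adjusted p = 0.0649), without M50 (0.0535), without M60 (0.0912) and with no replicate block (0.096).

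**Figure D1:**
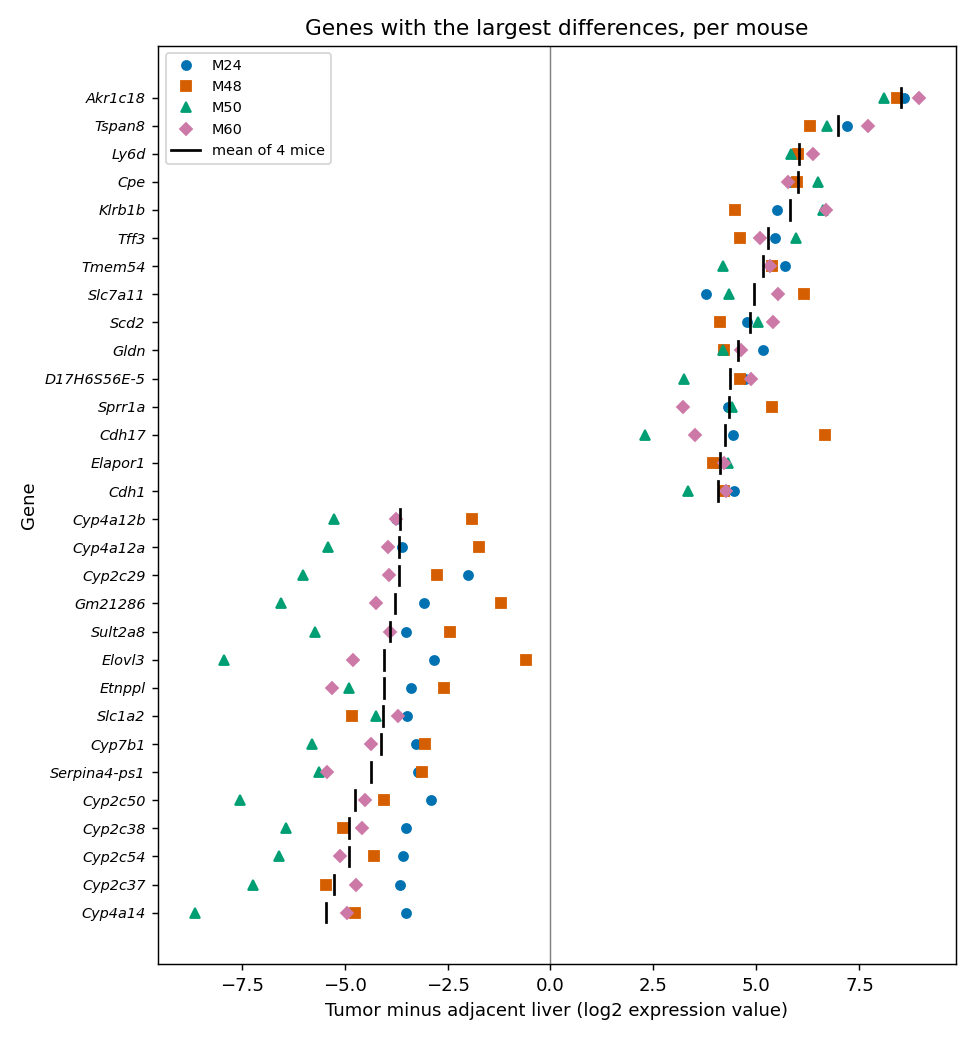
Tumor minus adjacent log2 differences of the 15 genes with the largest rise and the 15 with the largest fall, in each of the 4 mice (symbols) and on average (black bars). Akr1c18 lies between 8.09 and 8.95 in the 4 mice, while Elovl3 ranges from -7.92 in M50 to -0.59 in M48.

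In all, 1945 genes rose and 1874 fell, which together made up 31.9% of the 11963 tested genes. Of these, 3776 had the same sign in all 4 mice. A rise of at least 2-fold was seen in 545 genes and a fall of at least that size in 345. Without M60 the fit called 1238 genes higher and 1071 lower, and without M50 it called 1368 and 1170. With no replicate block the counts were 1743 and 1799. Camera called 16 of the 48 lists higher and 14 lower, and 0 lists passed when the correlation was estimated, with a lowest adjusted p = 0.356 and 6 lists at an unadjusted p under 0.05, while fry called 16 higher and 13 lower. Of these 29 lists 24 were also called by camera. The adjusted p-values with an estimated correlation, given below for the lists, come from the version with little power.

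**Figure D2:**
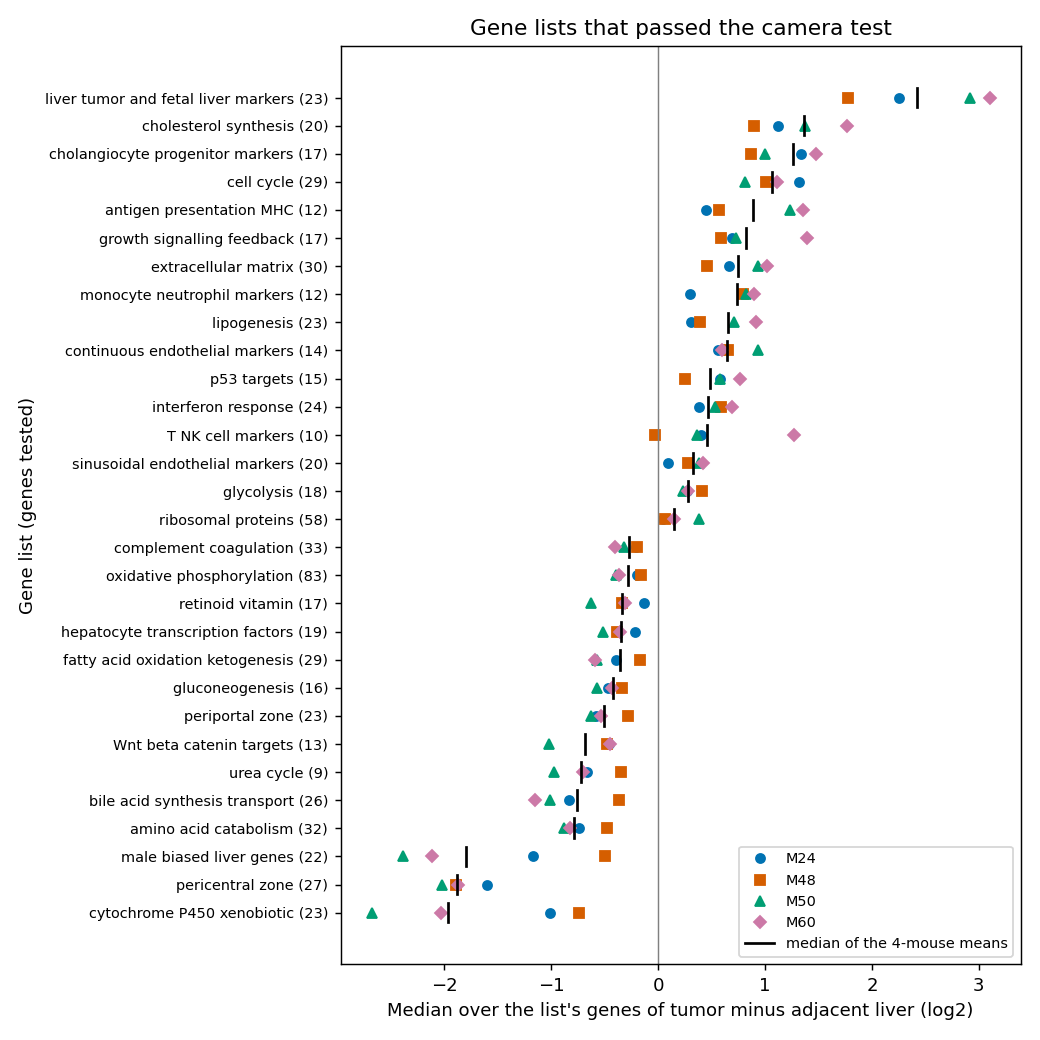
Median tumor minus adjacent log2 difference of each of the 30 gene lists past the camera threshold, in each mouse (symbols) and for the mean of the 4 mice (black bars). The tumor and fetal liver markers lie highest, with a median of 2.42, and the P450 list lies lowest, at -1.97.

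Genes known from liver tumors and fetal liver formed the group with the strongest shift. In this list 21 of 23 tested genes rose and 0 fell (22 and 0 when adjusted over the list alone), with a median of 2.42. The list had 29 measured members, and the filter used the mean over both tissues. A member low in adjacent tissue was therefore tested only if it was high in tumors, which favours rises. Among the untested members Igf2 (0.28), Igf2bp1 (0.11) and Igf2bp3 (0.26) differed little, Bex2 stood at 0.56, Cdkn3 at 1.17 and Bex1 at 1.93. The annexin Anxa2 rose by 3.54 (SE 0.0862), Golm1, a Golgi membrane protein, by 3.36, the glypican Gpc3 by 3.48 and alpha-fetoprotein (Afp) by 2.13. The Gpc3 difference ran from 1.13 in M48 to 5.42 in M60. By camera, the list had an adjusted p = 2.88e-15, and the adjusted p = 0.356 with an estimated correlation. Cholangiocyte and progenitor markers moved beside this group: 12 of 17 rose and 0 fell (13 and 0 when adjusted over the list alone), among them the keratin Krt23 at 2.46 and the transcription factor Sox9 at 1.36. Tspan8, Sox9, Cd24a and Prom1 belong to both lists. The bile duct keratin Krt7 did not pass, at 0.30 (adjusted p = 0.401). Camera returned an adjusted p = 1.66e-07 for this list, against an adjusted p = 0.356 with an estimated correlation.

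Enzymes of cholesterol synthesis were higher almost throughout the pathway. Of 20 tested genes 18 rose and 0 fell (19 and 1 when adjusted over the list alone), with a median of 1.36 and medians from 0.895 in M48 to 1.77 in M60. Squalene epoxidase (Sqle) rose by 3.70, lanosterol synthase (Lss) by 2.39, Dhcr7, which catalyses the last step, by 2.22 and Hmgcs1 by 1.61. For this list, camera gave an adjusted p = 3.47e-10, with an adjusted p = 0.356 with an estimated correlation. In lipogenesis 13 of 23 genes rose and 4 fell (13 and 4 when adjusted over the list alone). Scd2, ATP citrate lyase (Acly, 1.32) and the desaturase Fads2 (1.19) rose, while the regulators Mlxipl (-0.97) and Srebf1 (-0.71) fell. The camera adjusted p for lipogenesis was 0.00328, and 0.0599 with no replicate block, and the list had an adjusted p = 0.465 with an estimated correlation. In glycolysis 7 of 18 genes rose and 0 fell (8 and 0 when adjusted over the list alone), including the phosphofructokinase Pfkp at 2.33, hexokinase 2 (Hk2) at 1.60 and the pyruvate kinase Pkm at 1.11, and without M48 6 rose and 1 fell. Its camera adjusted p was 0.00447, with an adjusted p = 0.356 with an estimated correlation.

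Cell cycle genes rose in the tumors. Among 29 tested genes 21 rose and 1 fell (22 and 2 when adjusted over the list alone), with a median of 1.06 and a range of medians from 0.809 in M50 to 1.32 in M24. Cyclin D1 (Ccnd1) rose by 2.86, the replication helicase subunit Mcm6 by 1.73, Racgap1 of cytokinesis by 1.62 and the proliferation marker Mki67 by 1.79, and the repressor E2f8 fell by 1.05, the lower count being 2 without M48. Camera gave an adjusted p = 2.61e-08, against an adjusted p = 0.384 with an estimated correlation. Of 17 genes of growth factor signalling and its feedback, 14 rose and 0 fell (16 and 0 when adjusted over the list alone). The early response gene Egr1 rose by 2.65, the phosphatase Dusp4 by 1.74 and Myc by 1.42. This list had a camera adjusted p = 1.18e-06 and an adjusted p = 0.356 with an estimated correlation. Among 15 targets of p53, 10 rose and 1 fell (11 and 1 when adjusted over the list alone). The antiproliferative gene Btg2 rose by 2.88, the death receptor Tnfrsf10b by 2.37 and Phlda3 by 1.81, while Mdm2 did not pass at 0.26 and the death receptor Fas fell by 0.58. The camera adjusted p was 0.000316, with an adjusted p = 0.384 with an estimated correlation.

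The pericentral program of the liver lobule was lower. Of 27 pericentral genes 20 fell and 1 rose (21 and 2 when adjusted over the list alone), with a median of -1.88. Glutamine synthetase (Glul) fell by 2.13 (SE 0.115), and its other probe gave -2.27. Ornithine aminotransferase (Oat) fell by 2.98, the P450 enzymes Cyp1a2 by 3.37 and Cyp2e1 by 2.80, and the amino acid transporter Slc1a4 rose by 2.78. By camera, the list had an adjusted p = 3.16e-09, with an adjusted p = 0.356 with an estimated correlation. In the list of Wnt and beta-catenin targets 8 of 13 fell and 1 rose (8 and 1 when adjusted over the list alone). The receptor Lgr5 fell by 1.88, the transcription factor Tbx3 by 1.93 and Axin2 by 0.72, while Bmp4 rose by 1.18. Its camera adjusted p was 0.00155, with an adjusted p = 0.384 with an estimated correlation. Lgr5, Tbx3, Axin2 and Glul belong to both this list and the pericentral list, so the 2 results are not separate. Periportal genes went both ways, with 13 of 23 lower and 5 higher (13 and 5 when adjusted over the list alone). Pck1 of gluconeogenesis fell by 1.42 and Otc of the urea cycle by 1.56, while Cdh1 (4.06) and Aldh1b1 (2.12) rose. Camera called this list lower with an adjusted p = 0.00599, and an adjusted p = 0.465 with an estimated correlation and 0.0604 by fry.

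Cytochrome P450 genes of drug metabolism fell in 18 of 23 cases and rose in 0 (19 and 0 when adjusted over the list alone), with medians from -2.68 in M50 to -0.741 in M48. Besides the Cyp2c genes, the retinoic acid hydroxylase Cyp26a1 fell by 2.62 and the more distant Cyp2c23 by 2.70. In the camera test, the adjusted p was 8.14e-09, with an adjusted p = 0.384 with an estimated correlation. Cyp1a2, Cyp2e1, Cyp2c37, Cyp2c50 and Cyp2c54 of this list are also in the pericentral list. Of 26 genes of bile acid synthesis and transport 14 fell and 2 rose (15 and 2 when adjusted over the list alone). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 3.17 (adjusted p = 0.00116, and 0.0556 with no replicate block), Cyp27a1 by 2.17 and the nuclear bile acid receptor Nr1h4 by 1.12, while the oxysterol hydroxylase Cyp39a1 rose by 0.76. Camera returned an adjusted p = 0.000119, and an adjusted p = 0.384 with an estimated correlation. Cyp7a1 and Cyp27a1 are also in the pericentral list, Nr1h4 in that of hepatocyte transcription factors, and Cyp7b1 and Slco1a1 in the male-biased list. The result for bile acid genes is therefore not separate from those lists.

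Amino acid breakdown was lower in the tumors, with 23 of 32 genes down and 0 up (23 and 0 when adjusted over the list alone). Proline dehydrogenase (Prodh) fell by 2.69, Hpd of tyrosine breakdown by 2.67, the pyrimidine-degrading Dpyd by 1.92 and the glycine methyltransferase Gnmt by 1.66. The camera adjusted p was 4.23e-09, with an adjusted p = 0.384 with an estimated correlation. In the urea cycle 6 of 9 genes fell and 0 rose (6 and 0 when adjusted over the list alone). They included the first enzyme of the cycle, Cps1 (-0.84), and the ornithine carrier Slc25a15 (-0.96), whereas Arg1 did not pass at -0.27. Its camera adjusted p was 0.00149, with an adjusted p = 0.384 with an estimated correlation. Cps1, Otc, Asl and Arg1 belong to both this list and the periportal list. Gluconeogenesis had 8 of 16 genes lower and 1 higher (8 and 1 when adjusted over the list alone), with the glucose-6-phosphatase G6pc down by 1.96. For this list, camera gave an adjusted p = 0.00068, with an adjusted p = 0.356 with an estimated correlation. Pck1 and G6pc are in the periportal list too.

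Mitochondrial and fatty acid oxidation genes shifted down by smaller amounts in the median. Of 83 genes of oxidative phosphorylation 35 fell and 1 rose (43 and 1 when adjusted over the list alone), with a median of -0.28. The complex I subunits Ndufb8 (-0.64) and Ndufv1 (-0.62) were among them. Camera gave an adjusted p = 3e-09, with an adjusted p = 0.384 with an estimated correlation. In fatty acid oxidation and ketogenesis 14 of 29 genes fell and 2 rose (16 and 2 when adjusted over the list alone). The carnitine palmitoyltransferase Cpt2 fell by 0.90 and the peroxisomal thiolase Acaa1a by 0.84, and the hormone gene Fgf21 rose by 1.82. Cyp4a14, which fell by 5.46, is also in this list, whose median was -0.359. In the camera test, the adjusted p was 0.000316, with an adjusted p = 0.465 with an estimated correlation and 0.0618 by fry.

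Hepatocyte transcription factors were lower in the tumors. Among 19 factors 10 fell and 1 rose (11 and 1 when adjusted over the list alone). The nuclear receptors Nr1i3 (-1.77) and Rxra (-0.73) and Hnf4a (-0.35) fell, and Foxa3 rose by 0.90. By camera, the list had an adjusted p = 0.000229, and an adjusted p = 0.356 with an estimated correlation. Of 22 genes of secreted hepatocyte proteins 1 rose and 2 fell, and 0 rose and 0 fell when adjusted over the list alone or when M48 was left out of the fit over all genes. The 3 were Apoa1 (0.32), Apoa2 (-0.32) and Itih1 (-0.36), whose adjusted p-values without M48 were 0.127, 0.11 and 0.0596. Albumin (Alb) stood at 0.11 (adjusted p = 0.443) and transthyretin (Ttr) at -0.15 (adjusted p = 0.259), and camera gave this list an adjusted p = 0.443. Many of these genes were near the top of the measured range, where changes can be compressed: Alb had mean levels of 13.80 and 13.91, and the highest values of the arrays were 14.37 to 14.49. Of 33 complement and coagulation genes 15 fell and 2 rose (15 and 3 when adjusted over the list alone). The lectin Mbl1 fell by 1.65 and C8b by 1.23, while coagulation factor F11 rose by 1.59. The camera adjusted p was 0.00396, with an adjusted p = 0.465 with an estimated correlation.

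Genes expressed more in male than in female liver were lower in the tumors. Of 22 tested male-biased genes 17 fell and 2 rose (17 and 2 when adjusted over the list alone), with medians of -2.39 in M50, -2.12 in M60, -1.17 in M24 and -0.5 in M48. The adipokine gene Serpina12 (3.02) and Selenbp2 (1.15) rose. Camera returned an adjusted p = 1.39e-05, with an adjusted p = 0.465 with an estimated correlation and 0.0703 by fry. The adjacent tissue of M48 already had low levels: Elovl3 was at 3.57 there against 9.29 to 11.57 in the other adjacent samples and Cyp4a12a at 6.12 against 10.26 to 10.95. Sult2a8, which is not in the list, was at 6.73 there against 11.57 to 11.63. Without M48, 19 of the 22 genes fell and 2 rose. Female-biased genes went both ways, with 5 of 13 higher and 3 lower (5 and 3 when adjusted over the list alone). Their median was -0.35, their mean 0.538 and the direction of the camera test higher, at an adjusted p = 0.459. The steroid hydroxylase Cyp17a1 rose by 3.57, lipoprotein lipase (Lpl) by 2.66 and the peroxisomal transporter Abcd2 by 2.46.

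**Figure D3:**
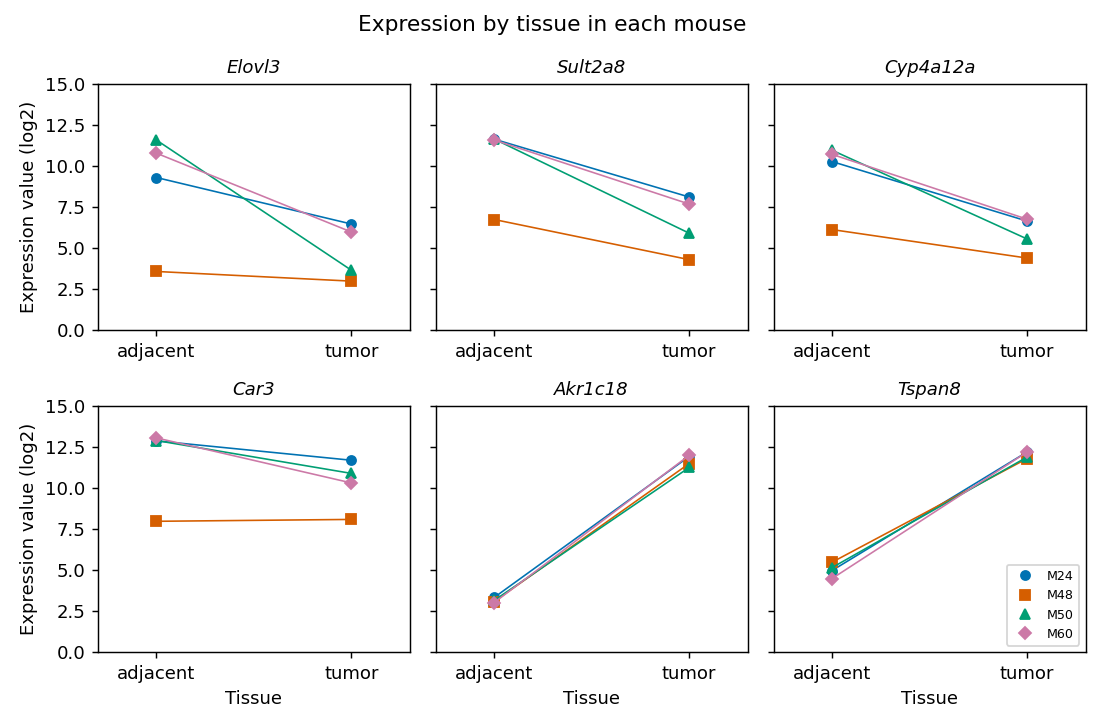
Log2 expression values of 6 genes in adjacent liver and tumor, with a line joining the samples of each mouse. Elovl3, Sult2a8, Cyp4a12a and Car3 are low in the adjacent tissue of M48 (Car3 7.97 against 12.86 to 13.04 in the others), while Akr1c18 and Tspan8 are low in all adjacent samples and high in all tumors.

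Markers of matrix, vessels and immune cells were measured beside these groups. In the extracellular matrix list 18 of 30 genes rose and 0 fell (19 and 0 when adjusted over the list alone). The basement membrane protein nidogen (Nid1) rose by 3.94, the collagens Col3a1 by 1.94 and Col4a2 by 1.25 and the matrix protein Sparc by 1.48. For this list, camera gave an adjusted p = 2.04e-07, with an adjusted p = 0.384 with an estimated correlation. Stellate cell and fibroblast markers did not shift together, with 4 of 19 higher and 2 lower (4 and 2 when adjusted over the list alone). Smooth muscle actin (Acta2) rose by 2.21 and vimentin (Vim) by 1.09, while Colec10 fell by 1.45. This list had a median of -0.233, a mean of 0.0467, and a camera adjusted p = 0.737 in the lower direction.

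Continuous endothelial markers rose in 8 of 14 cases and fell in 0 (9 and 0 when adjusted over the list alone), with Esm1 at 2.48 and endomucin (Emcn) at 1.46. In the camera test, the adjusted p was 0.000115, with an adjusted p = 0.384 with an estimated correlation. Sinusoidal endothelial markers rose in 11 of 20 and fell in 0 (11 and 0 when adjusted over the list alone), a count that was 7 without M48. The lymphatic receptor Flt4 rose by 2.43 and Lyve1 by 1.49, while Stab2 (0.29) and Clec4g (-0.10) did not pass. Camera gave an adjusted p = 0.00458, and an adjusted p = 0.465 with an estimated correlation.

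Monocyte and neutrophil markers were higher in 7 of 12 cases and lower in 0 (8 and 0 when adjusted over the list alone). The endotoxin co-receptor Cd14 rose by 3.74, Cybb by 1.79 and Gpnmb by 1.49, while the neutrophil genes S100a8 (-0.39) and S100a9 (-0.08) did not pass. The camera adjusted p was 0.00514, with an adjusted p = 0.384 with an estimated correlation. Resident Kupffer cell markers did not shift together: 7 of 19 fell and 1 rose, while 8 fell and 8 rose when adjusted over the list alone, and the medians ran from -0.322 in M24 to 0.589 in M50. The scavenger receptor Cd163 fell by 1.56. Marco (-1.29), Timd4 (-0.94) and Folr2 (-0.76) fell too, but with no replicate block their adjusted p-values were 0.151, 0.262 and 0.139. The macrophage gene Cd68 rose by 0.98. The Kupffer list had a median of 0.147, a mean of -0.16 and a camera adjusted p = 0.61 in the lower direction.

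Antigen presentation genes rose in 9 of 12 cases and fell in 0 (10 and 0 when adjusted over the list alone). The class II genes H2-Aa (1.47), H2-Ab1 (1.46) and H2-Eb1 (1.51) rose and B2m did not pass at 0.02. The class II genes are related in sequence. By camera, the list had an adjusted p = 0.000115, with an adjusted p = 0.438 with an estimated correlation. Interferon response genes rose in 12 of 24 cases and fell in 0 (14 and 0 when adjusted over the list alone), including the chemokines Cxcl9 (2.48) and Cxcl10 (1.61) and the sensor Ifih1 (0.82). Its camera adjusted p was 9.66e-05, with an adjusted p = 0.384 with an estimated correlation.

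Of the T and NK cell markers only Ccl5 rose, with 1 of 10 tested genes higher and 0 lower (0 and 0 when adjusted over the list alone), and 3 were higher without M48. Ccl5 rose by 1.25, a call lost without M24 (adjusted p = 0.0905), without M50 (0.0815) and with no replicate block (0.0539), and Nkg7 stood at 1.24 (adjusted p = 0.0626). The medians of this list ran from -0.0331 in M48 to 1.27 in M60. Camera returned an adjusted p = 0.0223, with an adjusted p = 0.569 with an estimated correlation and 0.174 by fry. Of 6 B and plasma cell markers 1 rose and 0 fell (1 and 0 when adjusted over the list alone), and 2 rose without M48. The gene that rose was Blnk at 2.40. The camera adjusted p of that list was 0.0504, and 0.00663 without M48, with an adjusted p = 0.569 with an estimated correlation and 0.171 by fry, both over all 4 mice.

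Genes of the imprinted Dlk1-Dio3 locus did not pass the test. The 3 tested members were Dlk1 at 0.29 (adjusted p = 0.149), Meg3 at 0.16 (adjusted p = 0.663) and Rtl1 at -0.03 (adjusted p = 0.895), so 0 rose and 0 fell (0 and 0 when adjusted over the list alone). Camera gave the list an adjusted p = 0.622. The Meg3 difference was 1.14 in M60 and between -0.32 and 0.01 in the other mice. Rian, a noncoding RNA of the locus, had a mean of 3.49 in adjacent tissue and 3.51 in tumors, below the filter, and Dio3 and Begain were also below it. Among 8 other imprinted growth genes 2 rose and 1 fell (2 and 1 when adjusted over the list alone), with Mest up by 1.22 and a camera adjusted p = 0.292. Grb10 rose by 0.84 and Peg3 fell by 0.89, and these calls were lost in 3 and 7 of 13 settings. For Grb10 the adjusted p was 0.0652 without M24, 0.0744 without M50 and 0.098 without M60. For Peg3 it was 0.0849 without M24, 0.0511 without M48, 0.116 without M60 and 0.147 with no replicate block.

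The 4 tumors shared much of their change. The differences of the 4 mice correlated across genes with r from 0.727 to 0.856, genes not being independent replicates. All 4 mice had the same sign in 49.9% of tested genes, where chance gives 12.5%. In 405 genes the difference was at least 2-fold in the same direction in every mouse, 266 higher and 139 lower, and the highest count under any other swap of labels within mice was 1. Such a swap turns the sign of a shared change in some mice, so that low count largely follows from the sharing and does not measure chance. No difference in spread between tumors and adjacent samples could be shown: the mean pairwise correlation was 0.9768 among tumors and 0.9767 among adjacent samples. Their difference of 9.805e-05 had a two-sided exact permutation p = 1 over 16 swaps, in a design whose smallest p is 0.125. Its sign turned without M48, to -0.008559, and with Spearman correlations, to -0.0001028.

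Xist had mean levels of 3.10 in adjacent tissue and 3.02 in tumors, below the filter. The Y-linked gene Uty had mean levels of 7.29 ± 0.0316 (SD) and 6.89 ± 0.215, which goes with the labelled male sex. It fell by 0.39 in tumors (adjusted p = 0.0311), a call that was lost without M24 (0.0872), without M50 (0.101) and without M60 (0.095), and Eif2s3y (-0.28) and Kdm5d (-0.26) did not pass. All 3 were lowest in M50, with differences of -0.68 for Uty, -0.96 for Eif2s3y and -0.65 for Kdm5d. In the other mice they ran from -0.36 to -0.18, from -0.15 to 0.005 and from -0.49 to 0.13. The cause was not tested.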

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

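The tests of the low male-biased genes in M48 were chosen after that result was seen. In each group of 4 samples, a value was singled out where its gap to the nearest other sample took most of the group's range, however small the gap. This happened in 24 of 410 groups of the named genes (5.85%, where chance gives about 5%) and in 9 of 96 groups of list means. The adjacent sample of M48 gave 12 of the 24.

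In the adjacent tissue of M48 the log2 levels of Sult2a8 (6.73), Gm21286 (5.55), Cyp4a12a (6.12), Cyp4a12b (6.96), Car3 (7.97), Car1 (4.96), Otc (9.95), Ldhd (8.72), Gsta3 (11.84), C8b (11.61) and Ndufb8 (8.39) lay below the other 3 adjacent samples. Rpl38 (10.46) lay only just above them, the nearest being at 10.39. The mean levels of the male-biased list (7.46) and the bile acid list (9.62) were low there, and those of the p53 targets (6.77), continuous endothelial markers (6.88) and growth signalling genes (6.28) were high. That sample also had 438 genes at least 2-fold from the mean of the other adjacent samples, against 60 to 130 in each of those. Metallothionein Mt2 was at 12.48 there against 7.12 to 9.20 in the others, the leptin receptor Lepr at 8.59 against 3.73 to 4.81 and Hmox1 at 10.07 against 7.28 to 7.94. Of 26 acute phase genes 23 lay above all other adjacent samples, as did 16 of 19 Kupffer cell markers (median deviation 1.46), 11 of 12 monocyte and neutrophil markers (1.08), 15 of 19 stellate cell markers (0.684) and 26 of 30 matrix genes (0.512). Below all others were 17 of 20 cholesterol synthesis genes (-0.896), 24 of 29 fatty acid oxidation genes (-0.581) and 65 of 83 oxidative phosphorylation genes (-0.213). The tumor of M48, measured on a separate array, deviated from the other tumors in related ways: the deviations of the 2 samples had r = 0.421 across genes, which are not independent replicates. Between different mice r ran from -0.378 to 0.189, a range that also held the values within M50 (0.0986) and M60 (0.111). In that tumor Elovl3 (2.98) and Sult2a8 (4.29) were the lowest of the 4 tumors, and the Kupffer list had a median deviation of 1.03.

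All 22 tested male-biased genes were lower in the adjacent sample of M48 than in the other 3, with a median deviation of -1.62. Tumor cells in that piece are argued against only in part as the source of these low levels. The 15 genes with the largest rise in tumors had moved by a median of only 0.0642 of the log2 distance to the tumors. Akr1c18, among them, was at 3.08 there against 3.02 to 3.33 in the other adjacent samples and a mean of 11.65 in tumors. These 15 genes were picked on rises that include this adjacent sample, which favours genes that are low in it. The small share is thus partly built in by the choice and is no independent test. Other values went toward the tumors: the deviation of that sample correlated across genes with the tumor difference of the other 3 mice at r = 0.333 (0.195 for M24, -0.0995 for M50 and -0.257 for M60), and 13 of 23 tumor and fetal liver markers and 17 of 29 cell cycle genes lay above all other adjacent samples, with 1 and 3 below. An array fault that depends on signal level would also lower other genes of like signal. It is argued against too, since the medians of 10000 gene sets matched on signal ran only from -0.373 to 0.212. The list's -1.62 lay below them all, but its low level had singled the list out, so that comparison is no independent test. A loss of the male pattern of liver expression may be involved, but the female-biased list had a median deviation of 0.333 with 7 of 13 genes above and 3 below all other adjacent samples, so that test leaves it open. A lower share of hepatocytes would lower other hepatocyte genes about as much. Among 6 hepatocyte lists, chosen after the values were seen, the lowest median deviation was -0.291 (periportal), with -0.102 for P450 genes, -0.187 for the urea cycle and -0.059 for pericentral genes. Lists outside the 6 lay lower, among them cholesterol synthesis (-0.896), fatty acid oxidation (-0.581), retinoid genes (-0.408) and bile acid genes (-0.336). The lists that hardly moved argue against a lower share as the whole source, but a part in it stays open. A fault of the adjacent array alone would leave the tumor array of M48 untouched, and the shared deviations (r = 0.421) speak against it as the whole source of the differences in M48. For the male-biased list it stays open, since that list deviated in that tumor by -0.386, close to -0.349 in the M50 tumor, and the design gives no group that sets M48 apart.

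In M24 adjacent tissue Etnppl (8.22) and P4ha2 (5.61) were low and Egfr (11.82) and Glul (12.48) were high. In M50 adjacent tissue Fgf21 (6.59) was high and Ccl5 (6.09) was low. Rian (3.33) was singled out there too, but it lay below the filter and the other adjacent samples all read 3.543. In M60 adjacent tissue Saa4 (11.72) was high and Emcn (4.57) was low. In tumors, M50 had a low Igf2r (8.24), a high Col3a1 (9.64) and a high mean of the imprinted growth genes (6.81). The M60 tumor had a high Prf1 (5.71) and a low mean of the hypoxia genes (7.155), and the M48 tumor had a high mean of the acute phase genes (10.64). The mean of the circadian clock genes in the M60 tumor (6.95) was singled out by a small gap, with the nearest tumor at 6.898.

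Probes without exactly 1 gene symbol were left out of the gene comparison. When every probe was fitted by itself, 632 of 3082 such probes passed the threshold, 336 higher and 296 lower, with a largest rise of 4.97.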

How the results depend on the processing

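The counts of genes changed in each mouse without a given mouse, and the list counts without M48, were chosen after seeing the data. Of the 186 named genes past the threshold, 162 kept their direction and their call in all alternatives run for them. The other 24 lost the call in at least 1 setting, 19 of them in a setting without a mouse, and 0 reversed. Among the 30 called lists 27 kept their call in the other fits tested with camera at the preset correlation, 0 reversed, and lipogenesis (adjusted p = 0.0599 with no replicate block), ribosomal proteins (0.0703 without M50) and retinoid genes (0.0583 to 0.0911 in 3 settings) lost it. With no replicate block 1743 genes were higher and 1799 lower, and with the mouse as a random block 1991 and 2048. The paired fit moved no count of calls by over 1.5 times. A minimum fold of 2 left 545 genes higher and 345 lower by construction. Leaving out a mouse gave 1238 to 1759 genes higher and 1071 to 1720 lower, with fewer samples in each fit. With an estimated correlation in camera, 0 lists were higher and 0 lower, with 6 at an unadjusted p under 0.05. Fry kept 24 of the 30 calls. It lost the male-biased, fatty acid oxidation, periportal, T and NK, retinoid and ribosomal lists (adjusted p = 0.059 to 0.174) and called 5 others: the female-biased, pancreas, circadian, growth hormone and iron lists. At 1.5-fold in every mouse 957 genes changed the same way, a looser rule by construction, and with 3 mice 425 to 584 genes did so at 2-fold. The tumor minus adjacent difference in mean correlation turned to -0.0001028 with Spearman correlations and lay between -0.008559 (without M48) and 0.003539 when a mouse was left out, and the cause was not tested. Median centring shifted the median of all genes to -0.0551 and the share of calls that were higher from 50.9% to 43.7%. Pseudocounts were not run because the values were already logs, and lists were not run with the random block, with eBayes without trend or robust, or on every probe, nor named genes on every probe. Without signal over background per probe, genes below the filter have no tested call.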

Other observations

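The tests of Klrb1b against immune cell markers and the tests of chromosome 15 were chosen after those results were seen. Several fixed lists moved in both directions. In the acute phase list 11 of 26 genes fell and 5 rose (13 and 6 when adjusted over the list alone; camera adjusted p = 0.0802), with the iron hormone hepcidin (Hamp) down by 3.60 and the serum amyloid Saa3 by 2.12, and the interleukin antagonist Il1rn up by 1.89. Iron and heme genes fell in 8 of 18 cases and rose in 3 (9 and 3 when adjusted over the list alone; camera adjusted p = 0.129), with the transferrin receptor Tfr2 down by 0.91 and the heme synthesis enzyme Alas1 by 1.07. Of 15 genes of the growth hormone and IGF axis 7 fell and 2 rose (7 and 2 when adjusted over the list alone; camera adjusted p = 0.0802), with Igfals at -2.56, the receptor Ghr at -1.23 and Igfbp1 at 3.65. Nrf2 and glutathione genes rose in 8 of 28 cases and fell in 6 (10 and 6 when adjusted over the list alone; camera adjusted p = 0.178), with the sulfiredoxin Srxn1 at 1.71 and Pgd of the pentose phosphate pathway at 1.80. Lipid storage genes rose in 6 of 17 and fell in 5 (6 and 5 when adjusted over the list alone; camera adjusted p = 0.737), with Plin3 at 0.98 and Fitm1 at -1.94.

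Retinoid and vitamin genes fell in 7 of 17 cases and rose in 3 (9 and 3 when adjusted over the list alone), with Rdh16 at -1.79 and Rdh11 at 1.47. Camera gave an adjusted p = 0.0412, against an adjusted p = 0.472 with an estimated correlation and 0.059 by fry, and the camera call was also lost with quantile normalization (0.0777), median centring (0.0911) and the 60% filter (0.0583). Of 58 ribosomal protein genes 5 rose and 1 fell (0 and 1 when adjusted over the list alone), with 1 higher and 1 lower without M48. Their median was 0.15, the camera adjusted p = 0.0037 (0.0703 without M50), and the adjusted p = 0.644 with an estimated correlation and 0.171 by fry, and pseudogene copies make single members uncertain. In the circadian clock list 5 of 16 genes fell and 2 rose (7 and 2 when adjusted over the list alone; camera adjusted p = 0.0572), with Tef at -1.18 and Hlf at -0.86, and 1 rose without M48. In the hypoxia list 5 of 16 rose and 2 fell (5 and 2 when adjusted over the list alone; camera adjusted p = 0.442), with Slc2a1 at 0.62 and Bnip3 at -1.11. Unfolded protein response genes rose in 4 of 23 and fell in 1 (4 and 1 when adjusted over the list alone; camera adjusted p = 0.455), with Trib3 at 1.71 and Ero1b at -1.33. Targets of YAP and TEAD rose in 3 of 10 and fell in 2 (3 and 2 when adjusted over the list alone; camera adjusted p = 0.442), with Ajuba at 1.55. Erythroid markers had 2 of 8 higher and 1 lower (3 and 1 when adjusted over the list alone), and 0 higher and 2 lower without M48. Their median was -0.0133, their mean -0.262 and the camera direction higher at an adjusted p = 0.887. Pancreas, fat and muscle markers had 1 of 10 higher and 2 lower (1 and 2 when adjusted over the list alone; camera adjusted p = 0.868), with the elastase Cela1 at 2.05, and 1 was lower without M48.

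Other splits of the 8 samples were fitted in the same way. Of 35 splits into 4 and 4, 3 put whole mice together and could not be fitted. The 8 splits that part all 4 pairs are the ones to set against the real split, and they are too few for a share under 0.05. Among them 1 split, the real one, gave 3819 genes past limma's threshold and 5090 at an unadjusted p under 0.05, and the highest other gave 0 and 497. In those other splits the mice with swapped labels carry the real difference into the residual variance. Their counts are thus held down by it and are not those of data without a difference. The remaining 24 part only 2 pairs, so with the mouse as a block their differences rest on 2 mice. The mice that are not parted add their real difference to the residual variance, and these fits are not comparable with the real one. Over all 32 fitted splits 1, the real one, reached 3819, and the highest other gave 0, or 2699 at an unadjusted p under 0.05.

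Klrb1b rose from 4.07 at the lowest to 10.9 at the highest level, and the lowest tumor level was 8.998. NK or T cells in the tumors are argued against as its source, because the highest rise among 10 tested T and NK markers was 1.25 against 5.82 for Klrb1b. Signal shared with related genes is argued against as well, since the highest rise among 5 other Klrb1 genes was 0.176 and their highest level was 3.59. It may therefore come from the tumor cells or from another cell type, which was not tested.

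The medians of 20 chromosomes in 4 mice were compared with gene sets matched on signal. Each of these 80 tests sets 1 tumor array against 1 adjacent array, takes its spread from gene draws that treat neighbouring genes as independent, and holds no replicate variation, so its p is too small where neighbours are regulated together. Of the 80 tests 24 had an adjusted p under 0.05, with 0 in M24, 8 in M48, 9 in M50 and 7 in M60. The medians of chromosome 9 (-0.136), 2 (0.127), X (-0.112) and 5 (-0.109) in M50, of 19 in M48 (-0.124) and of 8 in M48 (-0.0935) and M60 (-0.118) were among them, and these were not weighed further.

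Chromosome 15 had the largest shift in M48, M50 and M60. The median difference of its genes was 0.149 in M48, 0.224 in M50, 0.152 in M60 and 0.00382 in M24, over 496 genes. Against 10000 sets of other genes matched on signal, p was 1e-04 in M48, M50 and M60, the smallest the draws allow (adjusted p = 0.00057 over the 80 tests), and 0.087 in M24 (adjusted p = 0.18). A signal-dependent bias would move genes of like signal on other chromosomes as well, and the median of the 4-mouse mean, 0.134, lay above the highest matched set at 0.0493, but this repeats the comparison that singled out the chromosome and is no independent test. The same medians of the other 19 chromosomes, which hold such neighbours, lay between -0.0486 and 0.051. A single group of neighbouring genes is argued against, because the 248 genes on each side of the middle gene were both shifted, the lower set by 0.12. A gain of chromosome 15 in a share of the tumor cells may account for the shift, but copy number was not analysed here, and the shifts of other chromosomes leave other sources open.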
